A study of Arabidopsis thaliana with 6 samples.

How the data were processed

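Total RNA from whole Arabidopsis plants was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, with 5 µg of total RNA and 15.0 µg of fragmented cRNA per sample per the labels' protocols. There were 3 arrays of the Columbia-0 wild type and 3 of the cax1cax3 double mutant. The deposited values are log2 expression values per probe set. GCOS version 1.1.2 and RMA, which corrects background, normalizes between arrays and combines the probes of a set, are named in the submitters' processing notes without their role or order. Settings and filters were not given in the sources used here. The log2 scale was read from the deposited values, which ran from 3.35 to 14.5, and no further normalization or transformation was applied. Array medians ran from 7.03 to 7.08.

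The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which left 22746. Probe sets were named through the platform's annotation table, which can be old. It gave 1 gene for 13513 probe sets, several for 503 and no name for 8730. Of the probe sets with 1 gene, 13436 were updated through the gene number to the current symbol in a RefSeq gene table of assembly TAIR10.1, and 77 kept the annotation table's symbol. Together they named 13355 genes. A probe set with several genes or none was tested but given no gene name. No genomic coordinates were used. The annotation used paired no probe set with CAX1, CAX3 or another member of the CAX family, so no result could be assigned to them. Unnamed probe sets were tested, and whether any of them measures a CAX gene was not known here. The genotype labels therefore had no check from the mutated genes.

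Each probe set was compared between genotypes with limma's linear model and moderated test (lmFit and eBayes, limma 3.58.1 in R 4.3.3) over all 6 arrays, without covariates, and with Benjamini-Hochberg adjustment over all probe sets. A probe set with an adjusted p under 0.05 is called higher or lower in the mutant. All differences are the mutant minus the wild type on the log2 scale. Gene lists were tested with limma's camera, which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01. Adjustment was over the lists of one family, and camera with an estimated correlation and limma's fry were run beside it. For the lists, each gene was represented by its probe set with the highest mean. The design, 31 gene lists with 466 members, and the alternatives were chosen before the data were examined. The annotation named 67 of those members, so 13 lists had the 3 measured members that the test required, and 8 had none. Therefore 29 further lists were drawn up from the annotation before any expression value was compared between the genotypes. They are called added lists and were tested as a family of their own. Of the added lists, 6 share measured members with lists of the first family: WRKY factors (WRKY6, WRKY22 and WRKY53), plant defensins (PDF1.2 and PDF1.2b), expansins (EXPA4, EXPA7, EXPA8 and EXPA18), UGT glycosyltransferases (UGT78D2), tau glutathione S-transferases (GSTU25) and MADS-box factors (AGL24). Another 3 lists were drawn up after the results were seen, and they appear only among the other observations.

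Genes were named by a rule: the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between genotypes and whose higher group lay above the median level of all probe sets, up to 4 members of each list by adjusted p (the member with the largest change where none was called, with values only; others were added where they complete a short list), and 8 defence, senescence and photosynthesis markers, of which the annotation named PDF1.2. Background was judged from 27 probe sets for bacterial transcripts, whose median level was 4.04 and whose 95th percentile was 4.70. For arrays, their number limits the precision. On simulated data with the arrays' own spread over 22746 probe sets, the comparison of 3 arrays with 3 called 58.2% of 98 probe sets changed by 1 log2 unit and 95.1% of 102 changed by 2 log2 units, with 10 false calls. With no change simulated it made 0 calls. In the simulation of 13355 genes, the list test at the preset correlation called the 1 list that had been shifted and 0 of the others. Camera with an estimated correlation was not run on simulated data, so how often it misses a shifted list is not known. Both simulations drew each probe set or gene independently of the rest. In the data the estimated correlation within a list was as high as 0.941, for flavonoids and anthocyanins. The simulation therefore does not show how often lists of correlated genes are called falsely.

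The labels number the arrays 1 to 3 in each genotype without saying what a number marks or whether the samples came from separately grown plants, so the p-values measure the spread between these samples, which may be technical. Arrays with the same number deviated together from their genotype means, with correlations across probe sets of 0.433 for number 1, 0.292 for number 2 and 0.471 for number 3. Arrays with different numbers gave correlations of -0.411 to 0.12 between genotypes, where numbers 1 and 2 gave 0.12 and 0.116. The 3 deviations within a genotype cancel out. A difference shared by the arrays numbered 3 alone would therefore lower their correlations with numbers 1 and 2. It would also raise all those among numbers 1 and 2, where 0.433 and 0.292 stand against 0.12 and 0.116. The numbers may therefore pair the samples, on the evidence of the data alone. The planned fit without the number stayed the main one, and a fit with the replicate number as a block was run beside it. The other alternatives were quantile normalization, centring each array on its median, 2 filters on low levels, an intensity trend with a robust prior, an ordinary equal-variance test for each probe set, array weights, a random replicate block, a stricter adjusted p of 0.01, a change of at least 2-fold, 1 probe set per gene, the mean of a gene's probe sets, and leaving out each array in turn. One more, leaving out both arrays numbered 3, was chosen after seeing the data. Figures were drawn with matplotlib.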

Results

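The transcriptome of whole Arabidopsis plants was compared between the Columbia-0 wild type and the cax1cax3 double mutant. CAX1 and CAX3 encode cation/H+ exchangers of the vacuolar membrane that move calcium out of the cytosol. Each genotype was represented by 3 arrays. Plants were raised for 10 days on half-strength medium with 0.5% sucrose and then for 3 weeks in soil, in 16 hours of light at 22 °C, and the labels give their age as 40 days. Per the growth protocol, necrotic lesions had begun to appear on the mutant plants by then. The samples were whole plants, so a value can follow the share of an organ as well as expression within it.

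The arrays separated by genotype along the first principal component, which held 52.5% of the variance. The second component, with 28.1%, set both arrays numbered 3 apart from the others. Correlations across probe sets were 0.976 to 0.993 between arrays of the same genotype and 0.962 to 0.982 between genotypes. No result could be assigned to CAX1 or CAX3, because the probe annotation used paired no probe set with either. The genotype labels therefore had no check from the mutated genes.

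**Figure D1:**
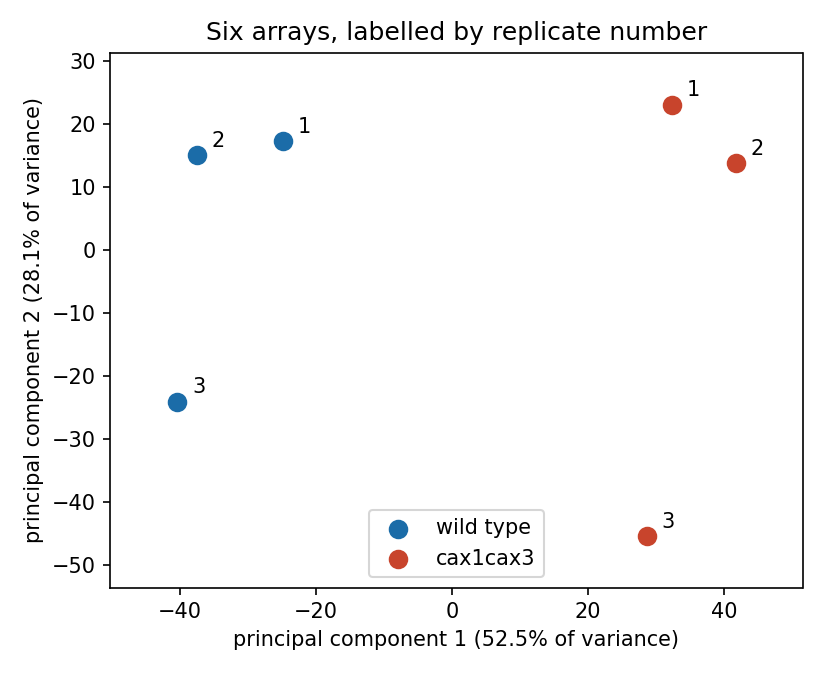
The 6 arrays on the first and second principal components of the log2 expression values (axis units are component scores), coloured by genotype and labelled by replicate number. The wild type lies between -40.4 and -24.8 on the first component and the mutant between 28.7 and 41.7, while the arrays numbered 3 lie at -24.0 and -45.3 on the second.

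The first question was which transcripts differed between the genotypes. CML41, CHI and RING1 stood among the largest rises in the mutant and GILT, DELTA-VPE and ATA27 among the largest falls. CML41, which encodes a calmodulin-like calcium sensor, rose 14.4-fold, from 7.47 ± 0.19 to 11.32 ± 0.13 (log2, SD, n = 3). CHI, a chitinase gene, rose 9.86-fold, and RING1, which encodes a RING-type ubiquitin ligase, rose 7.99-fold. GILT, named for a thiol reductase, went from 11.16 ± 1.14 in the wild type to 4.60 ± 0.19 in the mutant, a level within the range of the bacterial probe sets. In all, 532 probe sets were higher and 747 lower in the mutant by limma, and 289 and 347 of them by at least 2-fold. With the replicate number as a block the counts were 1053 and 1171, which included 513 and 710 of those called without it. Of the called probe sets, 273 higher and 373 lower ones were named with 1 gene. All 1279 had arrays that did not overlap between genotypes, as did 24.6% of all probe sets, where chance gives 10%.

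The other large rises were those of AT2G44240 (5.49 ± 0.33, log2 change ± SE, adjusted p = 0.00209), whose wild-type level of 4.43 lay within the bacterial range, SAL2 (4.06 ± 0.37, adjusted p = 0.00490), AMY1, an alpha-amylase gene (3.26 ± 0.38, adjusted p = 0.00859), AT2G32190 (3.21 ± 0.16, adjusted p = 0.00130), AT1G72060, AT1G15010 and AT3G47480, which codes for an EF-hand protein. Among the 10 largest rises, 8 stayed called when any 1 array was left out. AMY1 lost its call without mutant array 2 (adjusted p = 0.0517), and AT1G72060 lost it in 3 of 6 such fits (adjusted p up to 0.0721, without wild-type array 2). The lowest p of all belonged to the unnamed probe set 267093_at, which fell from 12.66 ± 0.05 to 7.15 ± 0.20 (adjusted p = 2.89e-05). It was singled out after its values were seen.

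**Figure D2:**
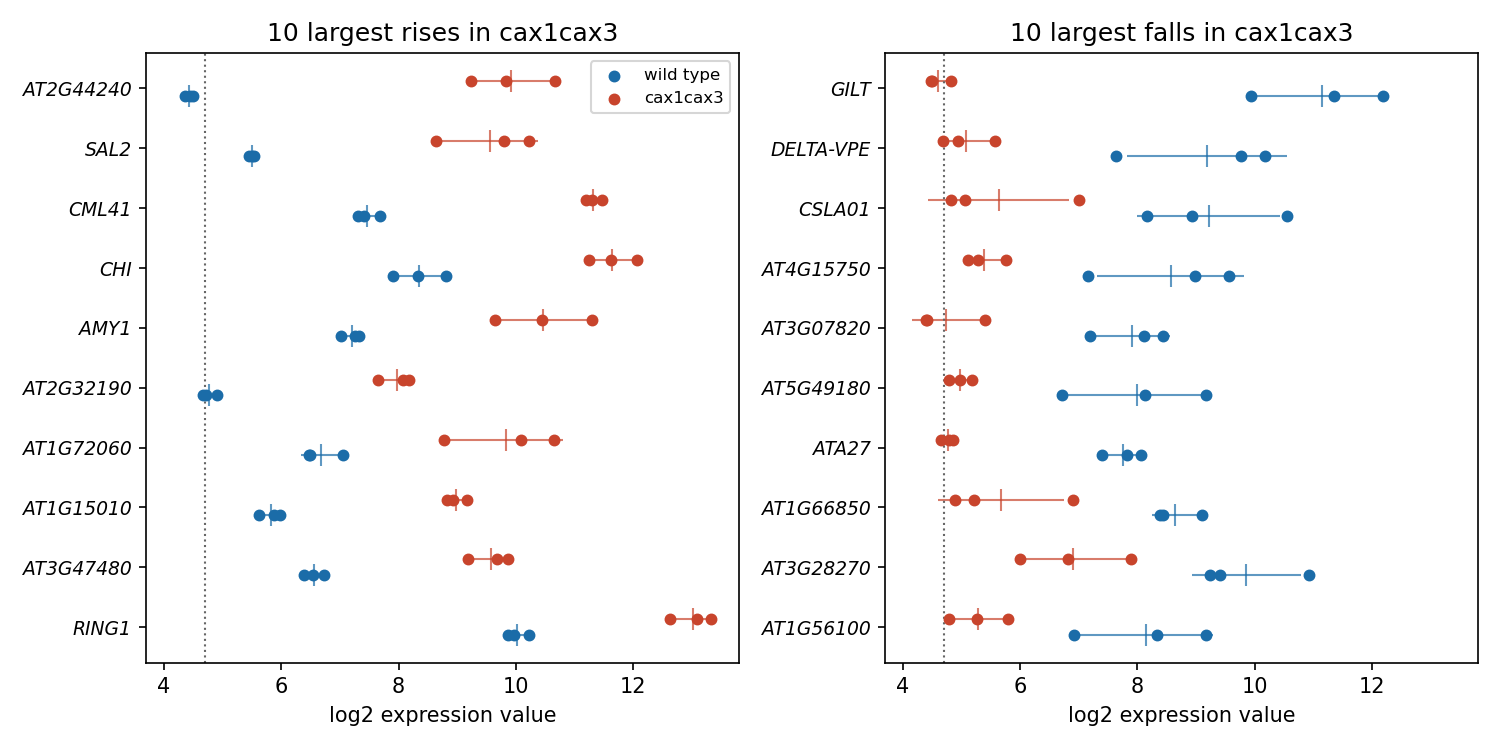
Log2 expression values of the 10 genes with the largest rises (left) and the 10 with the largest falls (right) in cax1cax3. Points are arrays (3 per genotype), ticks with bars are means ± SD, and the dotted line at 4.70 is the 95th percentile of the bacterial probe sets. No gene shown has overlapping genotypes, and several lie at or near the dotted line in the lower group.

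The counts depended on single arrays. Without wild-type array 1, 2 or 3, the probe sets higher in the mutant numbered 227, 141 or 319 and those lower 371, 165 or 438. Without mutant array 1, 2 or 3 there were 384, 108 or 797 higher and 469, 147 or 947 lower ones. Each such fit compares 2 arrays with 3, so a lost call can reflect the smaller number of arrays as well as the gene itself. Every called named gene had its highest adjusted p without mutant or wild-type array 2. Those fits called the fewest probe sets.

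The list of calcium sensors was called higher at the preset correlation and not with an estimated one. Of its 9 measured members, 5 rose and none fell, over all genes tested and adjusted over the list alone. Besides CML41, these were AT3G47480 (8.12-fold), AT5G39670 (5.30-fold), CML38 (3.43-fold) and CML37, which changed by 0.51 log2 units at levels within the bacterial range. The list's median change was 0.51 log2 units (camera adjusted p = 8.29e-06; adjusted p = 0.270 with an estimated correlation). CML41 and AT3G47480 stayed called without any 1 array (adjusted p up to 0.00421 and 0.0219). CML38 lost its call in 4 of 6 such fits and AT5G39670 in 3 of 6 (adjusted p up to 0.102 without wild-type array 2 and 0.0772 without mutant array 2). An added list of further calcium-binding proteins had 8 measured members with a median change of 0.94, of which 2 rose: AT2G41410 by 1.06 ± 0.15 and AT2G46600 by 0.95 ± 0.13 (list adjusted p = 0.00105; adjusted p = 0.429 with an estimated correlation). Both genes lost their calls without mutant array 2 (adjusted p = 0.0680 and 0.0638). Among 8 genes for glutamate receptor-like channels, GLR1.4 (3.62-fold), GLR2.8 and ATGLR1.2 rose and none fell, with a list adjusted p of 0.0388 (adjusted p = 0.612 with an estimated correlation). The wild-type levels of GLR2.8 and ATGLR1.2 lay within the bacterial range, and the 3 genes lost their calls in 2 (GLR1.4), 4 (GLR2.8) and 3 (ATGLR1.2) of 6 fits without 1 array. The list lost its call without wild-type array 2 or mutant array 3 (adjusted p up to 0.197), and with the 33.3% of probe sets with the lowest means left out (adjusted p = 0.330, median -0.0231). Its median was 0.34 higher in the arrays numbered 3 than in the others. VHA-A2 and VHA-A3, subunit genes of the vacuolar proton pump and the measured members of the list of calcium and proton pumps, were not called (log2 changes of -0.34 and -0.25, adjusted p = 0.187 and 0.513).

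The lists of salicylic acid response and pattern-triggered immunity were called higher at the preset correlation and not with an estimated one. The lists of jasmonate genes and defensins were not called higher (below). In the added list of genes that respond to salicylic acid, all 11 measured members had positive changes with a median of 1.70 log2 units. Over all genes tested 2 rose, CHI and the receptor kinase gene AT1G51890 (3.67-fold, adjusted p = 0.00543), and 8 did so adjusted over the list alone. The list had an adjusted p of 1.88e-06 (adjusted p = 0.429 with an estimated correlation and 0.0743 with fry). The same list was higher in the arrays numbered 3 than in the others, by a median of 1.28 log2 units (camera adjusted p = 1.21e-05, and 0.7 with an estimated correlation). With the replicate block 6 members rose. In the list fixed for salicylic acid signalling the annotation named SAG101 and GRX480. SAG101, which acts with EDS1 in immunity, rose 2.46-fold (adjusted p = 0.00441), and GRX480 was not called (0.45, adjusted p = 0.742). Of 3 genes of pattern-triggered immunity, the receptor-associated kinase gene BIK1 rose 2.32-fold (1.22 ± 0.12, adjusted p = 0.00525), while WRKY22 and EFR had changes of 0.80 and 0.36 and were not called (list adjusted p = 0.00877; adjusted p = 0.270 with an estimated correlation). Adjusted over the list alone, 2 of the 3 rose. SAG101, BIK1 and AT1G51890 stayed called without any 1 array.

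Of 3 genes linked to leaf senescence, WRKY53 (1.85 ± 0.38) and WRKY6 (0.97 ± 0.13) rose, also adjusted over the list alone, and SAG29 was not called (0.05). The list had an adjusted p of 0.0191 (adjusted p = 0.299 with an estimated correlation), which became 0.120 without mutant array 3 and was also lost without wild-type array 1. Array weights ended the list's call as well (adjusted p = 0.0839). WRKY53 lost its call in 5 of 6 fits that left out an array (adjusted p up to 0.160 without mutant array 2), and WRKY6 in 1 (adjusted p = 0.0606 without mutant array 2). In the added list of 6 WRKY factors, WRKY47 rose as well (2.22 ± 0.22, adjusted p = 0.00585), and the list adjusted p was 4.81e-04 (adjusted p = 0.429 with an estimated correlation). Of 23 cytochrome P450 genes CYP71B23, CYP71B24 and CYP71B6 rose, by 2.07, 1.06 and 0.58 log2 units. CYP71B23 stayed called without any 1 array, and CYP71B24 and CYP71B6 lost their calls in 5 and 4 of 6 such fits (adjusted p up to 0.136 and 0.0950). This list's adjusted p of 0.0399 became 0.0860 with the replicate block, 0.0512 with quantile normalization and 0.429 with an estimated correlation. It was lost in 4 of 6 fits without 1 array (adjusted p up to 0.201 without mutant array 3).

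Among the 10 largest falls, GILT and ATA27, which encodes a beta-glucosidase of the tapetum, stayed called without any 1 array. The other 8 lost their calls in at least 1 such fit. They were the gene for delta-VPE, a vacuolar processing enzyme of the seed coat (DELTA-VPE, -4.12 ± 0.64, adjusted p up to 0.0929 without mutant array 2), CSLA01, a glycan synthase gene (-3.58 ± 0.76, up to 0.173), AT4G15750, AT3G07820, a polygalacturonase gene (-3.18 ± 0.39, up to 0.0557), AT5G49180, AT1G66850, AT3G28270 and AT1G56100. The adjusted p of AT1G56100 went from 0.0366 to 0.0504 with the replicate block. The list of anther and pollen markers was called lower at the preset correlation and not with an estimated one. All 3 measured members had lower values in the mutant, and AT5G07230, the anther gene A9, was called (-0.71 ± 0.14, adjusted p = 0.0391). Its call was lost in 4 of 6 fits without 1 array (adjusted p up to 0.151 without mutant array 2). AMS and SHT had changes of -0.32 and -0.44 and were not called. Wild-type AMS lay within the bacterial range, and SHT went from 4.97 to 4.53, a mutant level within that range. The list adjusted p was 0.0116 (adjusted p = 0.270 with an estimated correlation), and 2 members were lower adjusted over the list alone and with the replicate block. The flowering-time gene AGL24 was not called (-0.12, adjusted p = 0.823).

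The added lists of RALF-like peptides, tubulins, SWEET transporters, serine carboxypeptidase-like proteins and trichome birefringence-like proteins were called lower at the preset correlation and not with an estimated one. Of 10 genes for RALF-like peptides, secreted signals that act on cell expansion, RALFL24 fell by 0.86 log2 units (adjusted p = 0.00845) and stayed called without any 1 array. RALFL25, to a level within the bacterial range, and RALFL26 fell as well, but each lost its call when single arrays were left out (adjusted p up to 0.127 and 0.163). RALFL26 had an adjusted p of 0.0689 with the replicate block. The list adjusted p was 0.00239 (adjusted p = 0.429 with an estimated correlation). Of 7 tubulin genes TUB6, TUB1 and TUB9 fell, by 0.74, 0.87 and 0.52 log2 units (list adjusted p = 5.84e-04; adjusted p = 0.429 with an estimated correlation). Of 14 genes for SWEET sugar transporters, SWEET10 (-0.92 ± 0.14) and SWEET14 (-0.54 ± 0.10, to a level within the bacterial range) fell, and 13 had negative changes (list adjusted p = 7.95e-04; adjusted p = 0.429 with an estimated correlation). The SWEET list was no longer called once the 33.3% of probe sets with the lowest means were left out (adjusted p = 0.0967) or the higher group was required above the median level (adjusted p = 0.35). Of 29 serine carboxypeptidase-like genes scpl20, SCPL43 and scpl47 fell, with a list median of -0.07 and 11 positive changes (list adjusted p = 0.00249; adjusted p = 0.447 with an estimated correlation). This list lost its call with the higher group required above the median level (adjusted p = 0.0557). Of 22 trichome birefringence-like genes, many of which act in wall acetylation, TBL38 and TBL36 fell, with a list adjusted p of 0.00485 (adjusted p = 0.447 with an estimated correlation), which became 0.0570 without mutant array 2. Apart from RALFL24, each gene named in this paragraph lost its call in at least 2 of 6 fits without 1 array.

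The list tests also called 15 genes for IQD calmodulin-binding proteins and 10 for H2B histones, Aurora kinases and spindle checkpoint proteins as lower, although no member of either was called. Their median changes were -0.24 and -0.20, each with a list adjusted p of 0.0399 (adjusted p = 0.612 and 0.576 with an estimated correlation). Quantile normalization ended both calls (adjusted p = 0.0575 and 0.0512), and each was lost in 3 of 6 fits without 1 array (adjusted p up to 0.207 without mutant array 2 and 0.189 without mutant array 1).

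**Figure D3:**
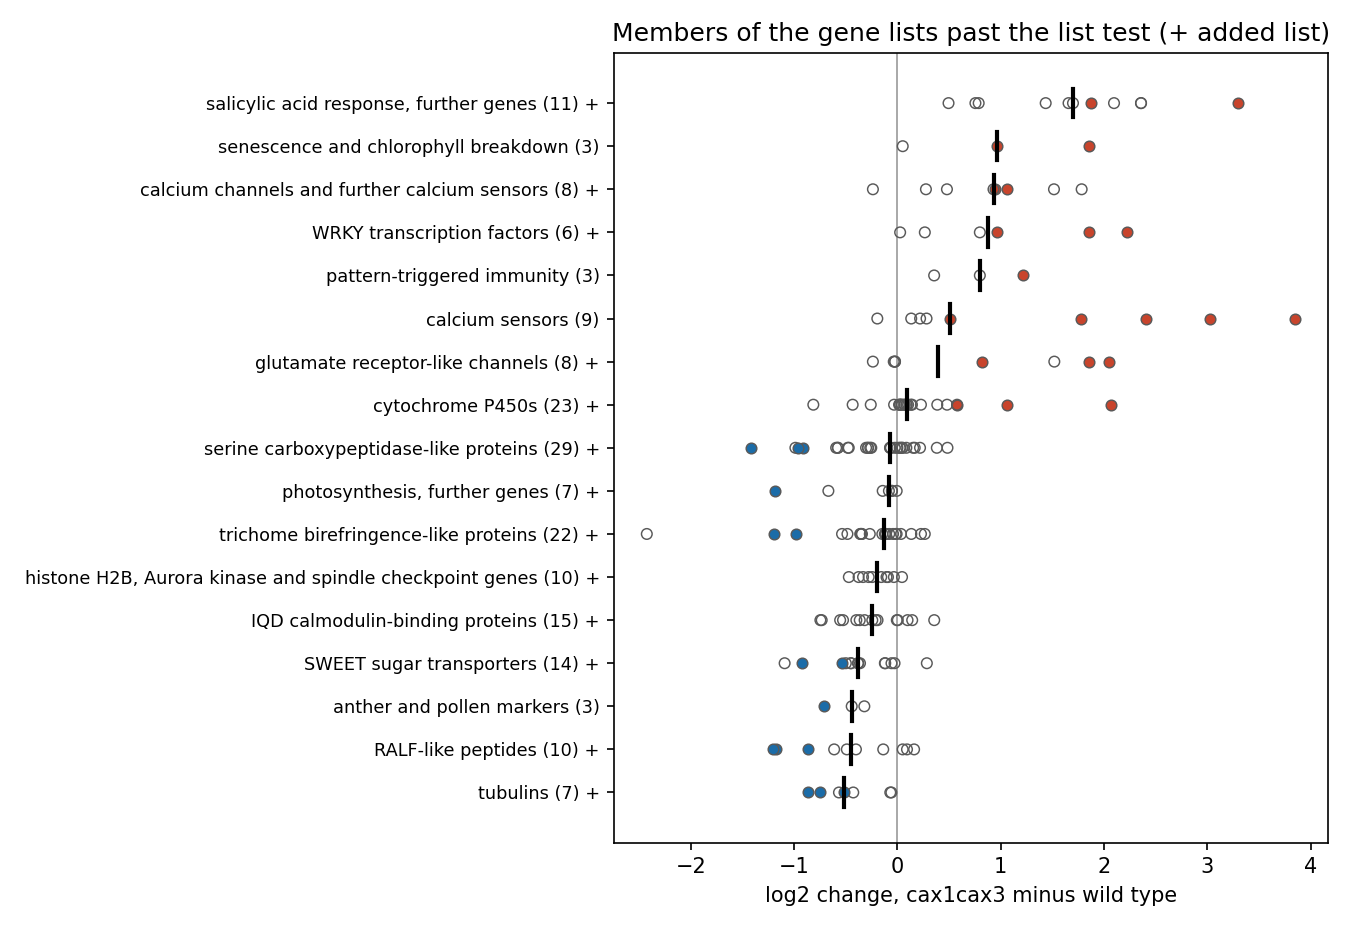
Log2 change of each measured member of the 17 gene lists past the list test (number of members in brackets, + for an added list). Points are genes, filled where the gene itself was called (red higher, blue lower), and black bars are list medians. Medians run from -0.52 for the tubulins to 1.70 for the salicylic acid list, and the called members of a list all lie on 1 side of 0.

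Of the 2 lists of photosynthesis genes, the added one was called lower at the preset correlation and the fixed one was not. The lists were not compared with each other. None of 7 members of the fixed list was called, and adjusted over the list alone 1 was, PRK (-0.42). Its median was -0.02, its mean 0.09 and camera's direction down (adjusted p = 0.897). In the added list, LHCB4.3, a light-harvesting gene, fell by 1.18 log2 units and the median was -0.08. Its adjusted p of 0.0399 became 0.0719 with quantile normalization and 0.535 with an estimated correlation. LHCB4.3 and the list each lost their call in 3 of 6 fits without 1 array (adjusted p up to 0.107 and 0.120 without mutant array 2).

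Another 3 fixed lists were not called over all 6 arrays without the replicate block and were called with it. The jasmonate and wounding list had a median of -1.45, and its 3 members PDF1.2, PDF1.2b and THI2.1 were not called. Adjusted over the list alone THI2.1 was lower, and it was also called with the block (-1.25, adjusted p = 0.0283). The list adjusted p was 0.141 without the block and 0.0147 with it. PDF1.2, a defensin gene, spread widely, from 6.64 to 12.70 in the wild type and from 5.40 to 9.46 in the mutant. The flavonoid and anthocyanin list went from an adjusted p of 0.221 to 0.0147 with a median of -0.43, and DFR, of that pathway, from 0.454 to 0.0119. The list of endoplasmic reticulum chaperones went from 0.127 to 0.0380 with a median of 0.44, and BZIP60 from 0.0782 to 0.0396. In the arrays numbered 3 the medians of the 3 lists were higher than in the others, by 3.74, 1.5 and 0.51. With the block and an estimated correlation these lists had adjusted p values of 0.430, 0.546 and 0.430. With the block, IQD28 (-0.75, adjusted p = 0.0388), the MADS-box gene AGL87 (-0.89, adjusted p = 0.0280) and AT2G31790 of glucosinolate synthesis (-0.47, adjusted p = 0.0372) were called as well, and the plant defensin LCR72 was not (adjusted p = 0.0607). The block also raised the number of called members from 3 to 7 among the serine carboxypeptidase-like genes, from 0 to 3 among the IQD genes and from 1 to 2 in the added photosynthesis list.

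The remaining fixed lists were not called. The list medians were 0.25 for oxidative stress (adjusted p = 0.381), 0.10 for cold response (adjusted p = 0.897), 0.06 for root markers (adjusted p = 0.681) and 1.06 for auxin response (adjusted p = 0.0756, and 0.0334 or 0.0321 without wild-type array 3 or mutant array 1). Adjusted over the list alone, WES1 of the auxin list was higher (1.06). In the auxin list the change of IAA29, 1.25, rested on mutant array 3, since the differences within numbers 1 and 2 were -0.19 and -0.22. The list of expansins, xyloglucan endotransglucosylases and pectin methylesterases had a median of -0.21, a mean of 0.36 and an adjusted p of 0.897. Of the added lists, 16 were not called, with adjusted p values of 0.159 or higher. They included the 69 chloroplast-encoded genes (median 0.11), 15 mitochondrion-encoded genes (0.11), 40 MADS-box factors (0.02), 7 further jasmonate-responsive genes (0.05), 8 heat shock genes (-0.09), 11 tau glutathione S-transferases (-0.19), 6 CHX cation/H+ exchangers (0.12), 9 U-box ubiquitin ligases (0.12) and 9 xyloglucan endotransglucosylases (0.09). Others held called members in spite of it. UGT87A2 rose 4.25-fold among 47 UGT glycosyltransferases (median 0.04), where UGT84A3 fell. UGT71B6 and UGT73D1 also rose, from wild-type levels within the bacterial range. PDF1.4 rose 4.48-fold and LCR69 2.13-fold in a list of 15 genes drawn up by symbol for plant defensins (-0.03). LCR72 of that list fell, to a level within the bacterial range. The list also took in the peptide deformylase genes PDF1A and PDF1B. TET8 rose and TET7 fell among 15 tetraspanins (0.03), and EXPB3 and EXPA16 fell among 18 expansins (-0.18). BGLU45 and BGLU40 fell among 20 beta-glucosidases (-0.03), ALDH3F1 fell among 8 aldehyde dehydrogenases (0.08), and AT1G08310 rose among 3 genes of phosphate starvation (0.50). Each of these genes lost its call in at least 1 of 6 fits without 1 array.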

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

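No called named gene changed direction in any fit, and neither did the list test of any called list. The median of the glutamate receptor-like list was -0.0231 with the probe sets of the lowest means left out, where the list was not called (adjusted p = 0.33). Of 74 named genes that were called, 20 stayed called without any 1 array, among them CML41, AT3G47480, CHI, BIK1, SAG101, WRKY47, GILT, ATA27 and RALFL24. Of 17 called lists, 10 did so. Without single arrays, the probe sets higher in the mutant numbered 108 to 797 and those lower 147 to 947, the lowest counts without mutant array 2 and the highest without mutant array 3. The fixed lists called numbered 3 to 6 and the added lists 9 to 13. Lists not called over all arrays gained a call without single arrays: the chaperones and auxin response among the fixed lists, and the chloroplast-encoded and mitochondrion-encoded genes, tau glutathione S-transferases and expansins among the added ones. The replicate block gave 1053 higher and 1171 lower probe sets and 7 fixed lists, and beyond the calls given with it in the report it changed no other call of a named gene or list. A random replicate block gave 1229 and 1542, and array weights 1286 and 1560. The ordinary equal-variance test, which borrows no spread from other probe sets, gave 7 and 12, and 72 of the 74 named genes lost their call. By construction fewer passed at an adjusted p of 0.01 (100 and 152), at 2-fold or more (289 and 347) and with 1 probe set per gene (267 and 361). With the higher group required above the median level, 1 fixed list and 6 added lists were called (the other 3 called fixed lists kept fewer than 3 members and were not tested, as was the anther list with the lowest means left out), and with the 33.3% of probe sets with the lowest means left out 8 added lists. Fry called 5 added lists. Of the 17 called lists, 8 lost their call with it, among them salicylic acid response (adjusted p = 0.0743). Fry tests a list against no change rather than against other genes. For the blocks, array weights, fry and the added lists under the level filters the cause was not tested. Camera with an estimated correlation called 0 fixed and 0 added lists, with 1 and 2 at an unadjusted p under 0.05. The estimate was below the preset 0.01 for anther and pollen markers (-0.333), RALF-like peptides (-0.00921) and cytochrome P450s (-0.00543). These lists lost their calls too, so a correlation above the preset was not the reason for them. The power of this version was not examined. Leaving out both arrays numbered 3, chosen after seeing the data, gave 973 higher and 1023 lower probe sets, 4 fixed lists, among them jasmonate and wounding (adjusted p = 0.0259), and 11 added lists, among them the mitochondrion-encoded genes. Of the 17 called lists, 4 lost their call with quantile normalization, 3 with array weights, 2 with the random block and 4 without both arrays numbered 3. Quantile normalization, median centring and the intensity trend kept all 4 counts within 1.5 times. CAX1 and CAX3, and the alternatives planned for them, were not run, because no probe set was named for either. The shifted log2 transformation planned for linear values was not run, since the values were already on a log2 scale. Signal over background limited falls such as that of GILT and rises such as that of AT2G44240, whose lower group lay at the bacterial level.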

Other observations

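The lists of tapetum, pollen and secondary wall genes, the control-transcript test of RNA degradation, the test of the anther list without the arrays numbered 3, the restriction of the calcium sensors to genes above the bacterial range, the use of other splits for the count of probe sets, the bootstrap intervals of the pollen and tapetum lists and the comparison of the arrays numbered 3 with the others were chosen after the results were seen.

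Of 5 genes of secondary cell walls measured, 3 fell in the mutant: IRX15 (-1.84 ± 0.17, adjusted p = 0.00523), IRX15-L (-1.77 ± 0.30) and GUT2 (-1.65 ± 0.20). GUT1 and AT5G66390 were not called (-0.27 and -0.13). IRX15 stayed called without any 1 array, and IRX15-L and GUT2 did not (adjusted p = 0.0967 without wild-type array 2 and 0.0518 without mutant array 2). Of 9 genes of the tapetum and pollen coat measured, 4 fell: ATA27, the extracellular lipase genes AT1G75880 (-2.29 ± 0.24) and AT1G75900 (-1.90 ± 0.18), and AT1G33430 (-0.78 ± 0.17). AT1G33430 lost its call in 5 of 6 fits without 1 array (adjusted p up to 0.164). The median was -0.78. Of 22 genes of pollen and the pollen tube 6 fell, among them AT3G07820, AT5G45880 (-2.76 ± 0.34) and the actin gene ACT11 (-1.29 ± 0.14), which other organs also express. TUB9, also among the 6, is a member of the tubulin list as well. AT3G07820 and AT5G45880 lost their calls without mutant array 2 (adjusted p = 0.0557 and 0.0558). The median of the 22 was -0.13. Adjusted over these 3 lists, the list p values were 3.26e-05, 2.48e-07 and 1.72e-04 (0.109, 0.136 and 0.144 with an estimated correlation). As the lists followed from genes already seen to fall, these tests are not independent evidence. Among probe sets without a gene name, 246302_at fell by 3.64 log2 units and 251176_at rose by 3.07.

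Of the 9 calcium sensors 5 rose in the mutant, and the list was called at the preset correlation and not with an estimated one. The whole-plant samples leave the mixture of organs as one possible source. A smaller share of flower tissue in the mutant would raise genes of the other organs alike. The median change of the 9 calcium sensors exceeded that of 14 nuclear photosynthesis genes by 0.559 log2 units, with a bootstrap 95% interval over genes of 0.216 to 3.07. The median is that of CML37, which lay within the bacterial range in both genotypes. Among the 8 sensors and 14 photosynthesis genes above that range in at least 1 genotype, the difference was 1.08 (interval 0.187 to 3.07). The intervals resample genes, so they do not measure the spread between plants. Many of the photosynthesis genes lay near the highest values on the arrays, where a rise may be compressed, and this was not tested. For the genes compared, the difference argues against that mixture as the whole cause only under 2 conditions. The photosynthesis genes must have had room to show a rise, and nothing else may have lowered them. The arrays numbered 3 did not carry the rise of the sensors: the lowest of the mean changes within the 3 numbers was 1.03. The mixture of organs stays open as far as compression hid a rise of the photosynthesis genes. Also open is whether the rise of the sensors may be tied to the genotype directly or to the lesions that the protocol describes. The genotype and the lesions were not tested apart, and the list's call was lost with an estimated correlation (adjusted p = 0.270).

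The fixed anther list was called lower at the preset correlation and not with an estimated one, with 1 of its 3 members called. Fewer or less advanced flowers on the mutant plants are a candidate explanation. If so, the tapetum and the pollen lists would both lie clearly below 0. The higher of their medians, that of the pollen list, was -0.132, with a bootstrap 95% interval of -0.386 to -0.035. A rule written before the test, on the medians alone, would count the pollen median against this explanation. The interval, added later, decides neither way. Of the list's members, 8 lay within the bacterial range in the wild type, and the median of the other 14 was -0.33. Background was not tested on the fixed anther list and remains open for it. That list's wild-type levels were 4.63 (AMS), 4.97 (SHT) and 5.95 (AT5G07230), against a bacterial 95th percentile of 4.70. Background also remains open for part of the tapetum list, although the rule written before the test, on its median alone, would count against background. The tapetum list's median wild-type level lay 1.05 log2 units above the bacterial 95th percentile (interval 0.177 to 3.07). Of its 4 called members, 3 lay over 2 log2 units above that percentile. The arrays numbered 3 as the source are argued against by the fixed anther list, whose median was -0.468 without both of them and -0.442 with all arrays, and which stayed called (adjusted p = 0.0259), although with an estimated correlation it was not called over all arrays (adjusted p = 0.270). Flower number and stage cannot be told apart here from lower expression within anthers.

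Both arrays numbered 3 deviated together. PDF1.2 was at 12.70 in the wild-type and 9.46 in the mutant array numbered 3, against 5.40 to 7.40 in the other 4 arrays, and BHLH101, an iron-deficiency regulator, was lower in them (-2.78 log2 units, adjusted p = 0.00632). With genotype in the model, 305 probe sets were higher and 352 lower in the arrays numbered 3, and the added lists of jasmonate-responsive genes (median 1.06, adjusted p = 2.02e-06; adjusted p = 0.554 with an estimated correlation) and salicylic acid response (median 1.28, adjusted p = 1.21e-05; adjusted p = 0.700 with an estimated correlation) were higher. A level-dependent trend left by the normalization is argued against by a Spearman rho of -0.0377 between the shared deviation and the mean level across probe sets. RNA degradation in these 2 arrays, which would raise the 3' minus 5' difference of control transcripts, is argued against as well: over 3 transcripts and both genotypes, all 6 differences between the array numbered 3 and the mean of the other 2 were negative, the highest at -0.0524. Whether the other 4 arrays were the more degraded ones stays open. No biological explanation was tested, since the labels do not say what the number marks.

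The 6 arrays can be split into 3 and 3 in only 10 ways, so no share of splits under 0.05 can be reached. The real split gave 1279 probe sets, and the highest of the other 9 gave 1. For the fixed lists the counts were 4 and 3, and for the added lists 13 and 11. In each of the 3 cases 1 split, the real one, reached the real count. The split with 11 added lists joined wild-type array 1 with mutant arrays 2 and 3. It parts all 3 same-numbered pairs, as the real split and 2 others do, and those 2 gave 4 and 1 added lists.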
